A study of Mus musculus with 4 samples.

How the data were processed

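Bulk RNA sequencing of cortical microglia from mouse embryos at embryonic day 16 was available as processed tables for 4 libraries, 2 labelled as floxed Bach1 controls (replicates 1 and 6) and 2 labelled as Bach1 conditional knockouts (replicates 2 and 5). Per the labels' protocols, total RNA was extracted with Trizol and sequenced on an Illumina instrument. The series text speaks of triplicates, and samples beyond these 4 were not analysed here. Groups and replicate numbers were taken from the sample titles. How the microglia were isolated, the strandedness of the libraries and the counting settings are not given in the sources used here. Reads of overlapping or antisense genes therefore cannot be told apart, and genes with near-identical copies, such as Gapdh with its pseudogenes, have uncertain counts.

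Per the submitters' processing notes, the tools were Bowtie2 2.2.3, TopHat2 2.0.12 and HTSeq 0.6.0 with the mm9 genome build, and their roles and settings are not given. The gene positions in the deposited tables nevertheless matched the GRCm38 annotation (90.4% identical among 21922 matched genes and 99.3% with starts within 5000 bp), so positions are given as GRCm38. The authors deposited 4 tables, each of 1 cKO library and 1 control library. Each table holds deposited raw read counts per Ensembl gene for both libraries. The deposited normalized values are CPM, each count scaled to a fixed total for its library, and a count of 0 was given the value of 0.5 reads by the authors. The deposited fold change is the ratio of the normalized values of the cKO and the control library, and the deposited log2 fold change is its log2. The deposited p-value and adjusted p-value come from a test that is not given in the sources used here, and the adjusted values lie below the p-values for 66.6% to 80.0% of genes. The authors' calls matched a p under 0.05 with a log2 change of at least 1 for every gene. The counts of a library were identical in both tables that hold it, and the library totals were recovered from the ratio of count to CPM. A table leaves out most genes with few reads in its pair of libraries; where both counts were known from other tables, the sum was at most 4 reads. No per-sample column was left unused.

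Counts were joined on the Ensembl gene ID, giving 21981 genes in any table and 18723 with a count in every library. Genes absent for a library were kept out of the tests. The totals ran from 17233115 to 19305078 reads. The floor of 3 reads was 0.172, 0.174, 0.173 and 0.155 CPM in that order.

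The genotypes were compared with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) on the deposited counts, with TMM factors (1.03, 0.917, 1.15 and 0.919), filterByExpr with a minimum count of 10, and Benjamini-Hochberg adjustment at 0.05. This left 15951 genes and 2 residual degrees of freedom. Tests were two-sided. An exact permutation of 2 against 2 libraries cannot reach 0.05, since it has only 3 distinct splits. The design, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except where said otherwise. The rule named Bach1, Hk2, Gapdh, Ldha, Lrrc15, Cd248, Cx3cr1 and Hmox1 whatever their values. It then named genes past the adjusted p with a mean of at least 5 CPM and both cKO libraries on the same side of both controls. Where none passed, it took the 6 with the smallest unadjusted p in each direction, leaving out symbols that start with Gm or LOC and a digit or end in Rik. It last named up to 4 members per list with the smallest adjusted p, ties going to the more abundant gene.

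The 34 lists covered glycolysis and lactate, BACH1 and NRF2 targets, the nuclear electron transport chain, the TCA cycle, cholesterol and fatty acid synthesis, hypoxia, the unfolded protein and integrated stress response, immediate early genes, inflammatory cytokines, interferon response, astrogenic signalling, cell cycle and extracellular matrix. Cell type lists covered microglia, activated microglia, border-associated macrophages, monocytes and neutrophils, lymphocytes, astrocytes, radial glia, intermediate progenitors, cortical excitatory neurons, Cajal-Retzius cells, interneurons, oligodendrocyte lineage, endothelium, pericytes and meningeal fibroblasts, erythroid cells, choroid plexus and brain regions outside the cortex. Sex-linked, ribosomal protein, mitochondrially encoded and histone genes completed them. Of 620 list genes tested, 6 stand in more than 1 list. Lists and annotation terms were tested with camera in limma 3.58.1 with a preset correlation of 0.01 and with an estimated correlation, and lists also with fry. Per-library list values are medians of log2(CPM + 0.5) deviations from the mean of the 4 libraries, with CPM divided by the TMM factors. Whether both cKO libraries lay on one side of both controls was judged on the same scale. CPM printed for single genes was not divided by these factors. Library similarity used log2 CPM with a prior count of 2.

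The alternatives were DESeq2 1.42.0 size factors in the edgeR fit, library size alone, TMM without hemoglobin, mitochondrially encoded and ribosomal protein genes, no filter on low counts, a minimum of 10 CPM on average, DESeq2's Wald test, limma-voom, edgeR's exact test, sex-linked genes left out, an adjusted p of 0.10, an added 1.5-fold minimum, and leaving out each library in turn. Where a library was left out, the lone library of its genotype was assumed to vary like the other genotype. Added after seeing the data were a neuron list score as a covariate, scaling on the microglia list without Cx3cr1, limma-trend on log2(CPM + 1), and, for the annotation terms, an estimated correlation and leaving out each library. Figures and overlaps were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

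The procedure was tested on simulated data for cKO against control, with 200 changed genes in counts drawn from the real means and totals. At the estimated dispersion of 0.425, it recovered 0 genes changed 2-fold (15844 tested) and 0 changed 4-fold (15884 tested). At a dispersion of 0.05 it recovered 14% of 2-fold (15971 tested) and 99.5% of 4-fold changes (15980 tested). Each simulated gene had the same dispersion, which real genes do not, so these shares may not hold for the real data. In a simulated set of 30 lists, a list raised 2-fold ranked 1 and 0 other lists were past the threshold (15953 genes tested). That set had a dispersion of 0.05 and genes that varied independently. It therefore cannot show how the list test behaves when the members of a list vary together.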

Results

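Microglia, the resident macrophages of the brain, were profiled by RNA sequencing from the cerebral cortex of mouse embryos at embryonic day 16. The libraries labelled control (control 1 and control 6) carried the floxed Bach1 allele, and those labelled cKO (cKO 2 and cKO 5) came from a Bach1 conditional knockout whose driver is named Cx3. Bach1 encodes a heme-binding transcriptional repressor of antioxidant and iron-handling genes. With 2 libraries per genotype, the design has a single contrast, cKO against control. The labels do not say that the libraries came from separate animals, so every p-value measures only the spread between these 4 samples. Library totals were 17472809 reads in control 1, 17233115 in control 6, 17310621 in cKO 2 and 19305078 in cKO 5. At this depth, 3 reads correspond to between 0.155 and 0.174 CPM (reads scaled to a common library total), and such floors cover counting error only. Genes with at least 1 read numbered 19831 and 18879 in the controls and 20602 and 18441 in the cKO libraries. The most abundant gene was Ctsb, a lysosomal protease gene, at 11890.3 CPM in control 1, 18628 CPM in control 6 and 17812 CPM in cKO 5. In cKO 2 it was Tuba1a, a tubulin gene abundant in young neurons, at 6821 CPM against 2371 CPM in control 1, 755 CPM in control 6 and 759 CPM in cKO 5 (Tuba1a was singled out after its values were seen). The 10 most abundant genes took 6.04% of reads in control 1, 8.17% in control 6, 4.61% in cKO 2 and 8.40% in cKO 5.

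The targeted gene was examined first. Bach1 (ENSMUSG00000025612, chromosome 16, 87698945 to 87733346 on the plus strand, in GRCm38 coordinates) had 45.8 CPM (800 reads) in control 1 and 21.6 CPM (372 reads) in control 6. It had 29.98 CPM (519 reads) in cKO 2 and 35.4 CPM (683 reads) in cKO 5, so both values in libraries labelled cKO lay between the control values. The means were 33.7 ± 17.1 CPM in control and 32.7 ± 3.82 CPM in cKO (SD, n = 2 each). The log2 fold change was −0.07 ± 0.47 (SE), with an adjusted p of 0.9997 in edgeR's quasi-likelihood test. A count per gene includes exons outside the floxed part, so these values do not check the genotype labels, and each direction given for cKO rests on the labels alone. The sex-linked genes differed within each genotype: Xist, transcribed from the inactive X chromosome, had 181 CPM in control 1 and 275 CPM in cKO 5 and no reads in control 6 or cKO 2. The Y-linked gene Ddx3y had 112 CPM in control 6, 143 CPM in cKO 2 and no reads in the other libraries. The libraries of a genotype were therefore not repeats of the same RNA.

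The comparison of genotypes asks which microglial genes respond to loss of Bach1, and in particular the glycolytic genes that the study connects to lactate and astrocyte formation. Cx3cr1, the fractalkine receptor of microglia, averaged 4746 ± 584 CPM in control and 1751 ± 1421 CPM in cKO (SD, n = 2 each). The immediate early genes Fos and Egr1 had lower values in both cKO libraries, while the antioxidant gene Hmox1 and the glycolytic gene Hk2 did not separate the genotypes. Microglial markers had their lowest values in cKO 2, and neuronal markers had their highest there. No single gene passed the threshold. Of 15951 genes tested with edgeR's quasi-likelihood test, 0 were higher and 0 lower at an adjusted p under 0.05, and the smallest adjusted p was 0.9997. At an unadjusted p under 0.05 there were 49 genes (28 higher, 21 lower in cKO), where 797.55 would be expected by chance. The other tools also gave 0 genes after adjustment, with 112 unadjusted genes in DESeq2, 37 in limma-voom, 94 in edgeR's exact test and 54 in limma-trend on log2(CPM + 1). The libraries of each genotype varied widely, with a common dispersion of 0.425 (a biological coefficient of variation of 0.652). On counts simulated with that dispersion for every gene, 0 of 200 genes changed 4-fold were recovered. Changes of this size were thus not detectable at that dispersion. Without cKO 5, 1784 genes had an unadjusted p under 0.05, and without cKO 2, 583 did, both with 0 genes after adjustment in edgeR.

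Among the genes named before the data were examined, none passed the threshold (adjusted p = 0.9997 for each in edgeR). Hk2 (ENSMUSG00000000628, chromosome 6, 82725025 to 82774454), which encodes the hexokinase that starts glycolysis, had 93.7 and 119 CPM in the controls, 33.4 CPM in cKO 2 and 104 CPM in cKO 5. Its log2 fold change was −0.63 ± 0.72 (SE). Ldha (ENSMUSG00000063229, chromosome 7, 46841475 to 46855627), the lactate dehydrogenase subunit gene, had 1297 and 1479 CPM in the controls against 818 CPM in cKO 2 and 1544 CPM in cKO 5, a log2 fold change of −0.26 ± 0.62. Gapdh (ENSMUSG00000057666, chromosome 6, 125161715 to 125166467) had 46.2, 50.9, 34.5 and 66.8 CPM in control 1, control 6, cKO 2 and cKO 5. This glycolytic gene has many near-identical processed pseudogenes, so its count is uncertain. Hmox1 (ENSMUSG00000005413, chromosome 8, 75093621 to 75100589), the heme oxygenase gene that BACH1 represses, had 558 and 590 CPM in the controls. The cKO values stood on either side of these, at 190 CPM in cKO 2 and 1064 CPM in cKO 5, a log2 fold change of 0.16 ± 0.97. Lrrc15 (ENSMUSG00000052316, chromosome 16, 30269302 to 30283256), which encodes a leucine-rich repeat membrane protein, had 8.01 and 5.22 CPM in the controls, 3.70 CPM in cKO 2 and no reads in cKO 5, where 3 reads would be 0.155 CPM. Its fold change, −2.05 ± 1.96 on the log2 scale, was smaller than 2 standard errors. Cd248 (ENSMUSG00000056481, chromosome 19, 5068078 to 5070637), an endosialin gene of pericytes and fibroblasts, had 213 and 59.0 CPM in the controls, 232 CPM in cKO 2 and 9.01 CPM in cKO 5. Cx3cr1 (ENSMUSG00000052336, chromosome 9, 119901616 to 120069879) had 4333 and 5158 CPM in the controls, 747 CPM in cKO 2 and 2756 CPM in cKO 5, a log2 fold change of −1.43 ± 0.94. Cx3cr1 and Lrrc15 were the genes of this group with both cKO values below both control values. Judged on TMM-normalized CPM, such a separation was found for 1329 genes on the higher and 1219 on the lower side (15.97% of those tested). Chance gives 33.3% over both sides if the libraries are interchangeable.

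**Figure D1:**
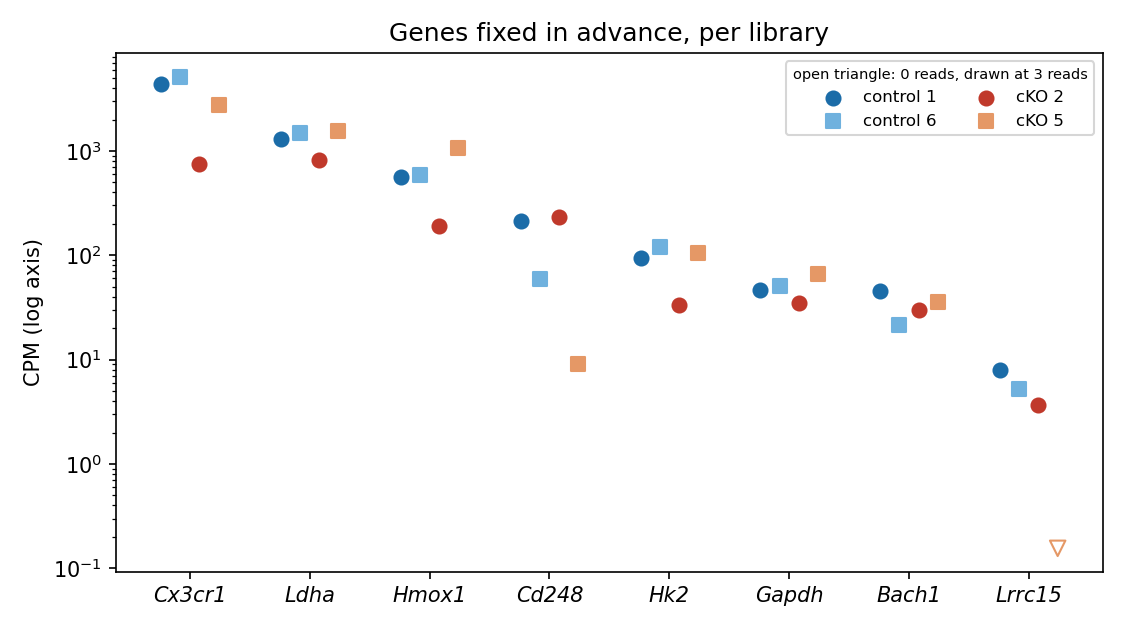
CPM (log axis) of the 8 genes named before the data were examined, with 1 point per library, controls and cKO side by side; an open triangle marks 0 reads, drawn at the value of 3 reads. The Bach1 values of the cKO libraries (29.98 and 35.4 CPM) lie between those of the controls (21.6 and 45.8 CPM), and both Cx3cr1 values of the cKO libraries (747 and 2756 CPM) lie below the control values.

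Since no gene passed, the genes with the smallest unadjusted p on each side were described as not past the threshold. On the higher side, Gspt2, a translation termination factor gene, had 2.35 and 2.38 CPM in the controls and 8.67 and 10.1 CPM in cKO, a log2 fold change of 1.93 ± 0.60 (unadjusted p = 0.0288, edgeR). Aqp4, the astrocyte water channel gene, had 2.98 and 1.39 CPM in the controls and 10.4 and 6.11 CPM in cKO. Erdr1 went from 5.67 and 5.86 CPM to 15.8 and 14.1 CPM, and lies in the region shared by the sex chromosomes, so its reads may be split between copies. The others on this side were Them4 (log2 fold change 1.34), the kinase gene Dyrk3 (1.65) and the helicase gene Pif1 (0.91). On the lower side, Egr1 had 85.5 and 77.1 CPM in the controls and 25.2 and 39.1 CPM in cKO, a log2 fold change of −1.37 ± 0.43 (unadjusted p = 0.0308, edgeR). Fos had 156 and 70.1 CPM in the controls and 25.0 and 40.9 CPM in cKO (log2 fold change −1.78 ± 0.57), and Junb had 139 and 116 CPM against 62.6 and 75.6 CPM. The others were Sigirr, a negative regulator of interleukin receptor signalling (−0.90), Lrch1 (−0.76) and the transcription factor gene Prdm1 (−1.09).

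The 34 gene lists were tested with camera, and 14 were past an adjusted p of 0.05 with the preset correlation of 0.01. None was past with an estimated correlation, where the smallest adjusted p was 0.894, and fry gave none in 1 direction (smallest adjusted p 0.988) or in either direction (0.956). In every list, 0 members were past the threshold over all genes and 0 adjusted over the list alone (edgeR). The list results below are therefore relative to other genes and hold only at the preset correlation. Scaling on the microglial markers, chosen after seeing the data, in place of all genes moved the median log2 fold change of all genes from 0.03 to 1.10, and list directions are given relative to that median. With the excitatory neuron list's score as a covariate (also chosen after seeing the data), 1 residual degree of freedom was left. The excitatory neuron list lost its call there by construction, and the other neural lists, which vary with it, lost theirs too, so this fit is no evidence on them. The glycolysis, cholesterol and activated microglia lists were not past the threshold in that fit either. The glycolysis median hardly changed (−0.18 against −0.20), while the cholesterol median went from 0.32 to 0.06 and the activated microglia median from −0.23 to −0.13.

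Microglial markers fell as a group in cKO (camera adjusted p = 3.2e-07; adjusted p = 0.894 with an estimated correlation), with negative values for 24 of 24 members and a median log2 fold change of −0.51. The values came from cKO 2. Csf1r, the receptor that microglia need for survival, had 5365 and 7212 CPM in the controls, 1936 CPM in cKO 2 and 6621 CPM in cKO 5. P2ry12, a purinergic receptor gene of microglia, had 3346, 5871, 1071 and 4184 CPM in the same order, and the complement gene C1qa 4213, 5877, 1591 and 6924 CPM. Relative to the mean of the libraries, the list's median was 0.04 in control 1, 0.82 in control 6, −1.48 in cKO 2 and 0.64 in cKO 5 (log2). Without cKO 2 the list's median was 0.22 and camera placed it higher (adjusted p = 0.0254), and without control 6 the median was −0.10 (adjusted p = 0.346). The list of activated and axon-tract microglia had the same arrangement, with 13 of 17 members negative, a median of −0.23 and per-library values of −0.06, 0.63, −1.34 and 0.74 (camera adjusted p = 0.0116; adjusted p = 0.894 with an estimated correlation). Its members Apoe and Spp1 had 2681 and 974 CPM in cKO 2 against 9547 and 3736 CPM in cKO 5. Without cKO 2 its median was 0.49, and without control 6 it was 0.03; the call was also lost with DESeq2 (camera adjusted p = 0.0702) and edgeR's exact test (0.0622). Border-associated macrophage genes deviated by −0.05 and 0.21 in the controls, −0.96 in cKO 2 and 1.01 in cKO 5, with Mrc1 at 370 CPM against 165 and 204 CPM in the controls and 85.9 CPM in cKO 2. That list had 8 of 11 members positive and a median of 0.32 (camera adjusted p = 0.492), and camera placed it higher without cKO 2 (adjusted p = 1.9e-08) and lower without cKO 5 (4.5e-04). Monocyte and neutrophil genes had 5 positive and 6 negative members (median −0.00, camera adjusted p = 0.432), and both tested lymphocyte genes were negative (median −0.19, camera adjusted p = 0.255).

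Neural markers rose as groups in cKO at the preset correlation, and their per-library values placed cKO 2 above every other library. All 20 markers of cortical excitatory neurons were positive, with a median log2 fold change of 1.37 (camera adjusted p = 4.2e-06; adjusted p = 0.894 with an estimated correlation). Neurod6, a transcription factor gene of these neurons, had 435 and 134 CPM in the controls, 1653 CPM in cKO 2 and 95.4 CPM in cKO 5, and Dcx, a microtubule gene of migrating neurons, had 226, 59.5, 616 and 58.1 CPM. The median deviation of the list was 0.29 in control 1, −1.0 in control 6, 2.00 in cKO 2 and −1.18 in cKO 5. Intermediate progenitor markers (10 of 10 positive, median 1.30), interneuron markers (11 of 11, median 1.18) and Cajal-Retzius markers (6 of 6, median 2.04) gave camera adjusted p-values of 0.00264, 4.3e-04 and 4.3e-04. With an estimated correlation each had an adjusted p of 0.894. Dlx2, an interneuron gene, had 98.5 CPM in cKO 2 and 12.9 CPM in cKO 5, and Calb2, a calretinin gene, had 40.5 and 2.49 CPM. Radial glia markers, 14 of 14 positive with a median of 0.98, had a camera adjusted p of 0.0150 (adjusted p = 0.894 with an estimated correlation; 0.0504 in limma-trend). Their member Fabp7 had 72.0, 16.4, 193 and 11.1 CPM in control 1, control 6, cKO 2 and cKO 5. Without cKO 2, the medians were −0.96 for excitatory neurons, −0.93 for intermediate progenitors, −0.49 for interneurons and −1.22 for radial glia, and 0.17 for Cajal-Retzius cells, with camera placing the excitatory neuron, intermediate progenitor and radial glia lists lower (adjusted p = 1.5e-04, 0.0254 and 0.00494). Without control 6, camera left the Cajal-Retzius list alone among the 5 past the threshold (adjusted p = 0.0331). Astrocyte markers were positive in 12 of 17 members (median 0.87, camera adjusted p = 0.238), with Slc1a3, a glutamate transporter gene, at 119, 49.7, 306 and 29.5 CPM. That list was past the threshold, as higher, with DESeq2 (camera adjusted p = 0.00778) and edgeR's exact test (0.0124). It had a median of −1.82 without cKO 2 and −0.70 with the neuron list score as a covariate, and was then placed lower by camera (adjusted p = 1.5e-06 and 6.9e-05), while without control 1 it was 1.94 and without cKO 5 1.77. Oligodendrocyte lineage markers had 4 positive and 5 negative members, a median of −0.03 and a mean of 0.49 (camera higher, adjusted p = 0.613).

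Vascular and matrix genes were also higher in control 1 and cKO 2 than in control 6 and cKO 5, with the list medians highest in control 1 and not in cKO 2. Endothelial markers fell as a group (12 of 12 negative, median −0.59, camera adjusted p = 0.0244; adjusted p = 0.894 with an estimated correlation). Cldn5, the tight junction gene of brain vessels, had 1535 CPM in control 1, 279 CPM in control 6, 1147 CPM in cKO 2 and 146 CPM in cKO 5. Extracellular matrix genes fell too (16 of 21 negative, median −0.53, camera adjusted p = 0.0150; adjusted p = 0.894 with an estimated correlation), with the basement membrane collagen gene Col4a1 at 818, 106, 644 and 60.04 CPM. Leaving out control 1 gave positive medians of 0.95 for endothelial and 1.06 for matrix genes, and leaving out cKO 5 gave 0.15 and 0.19; only the endothelial list was past the threshold in 1 of these fits, as higher without control 1 (camera adjusted p = 0.0484). With all libraries, the endothelial call was lost in limma-voom (camera adjusted p = 0.0537) and limma-trend (0.0504). Pericyte and meningeal fibroblast genes had 10 of 12 negative members (median −0.43, camera adjusted p = 0.336), with Rgs5 at 2669, 525, 2487 and 190 CPM. Camera placed them lower without control 6 or cKO 2 (adjusted p = 6.3e-06 and 3.9e-09) and higher without control 1 (0.0444). Erythroid genes had 8 of 9 negative members (median −0.41, camera adjusted p = 0.125).

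**Figure D2:**
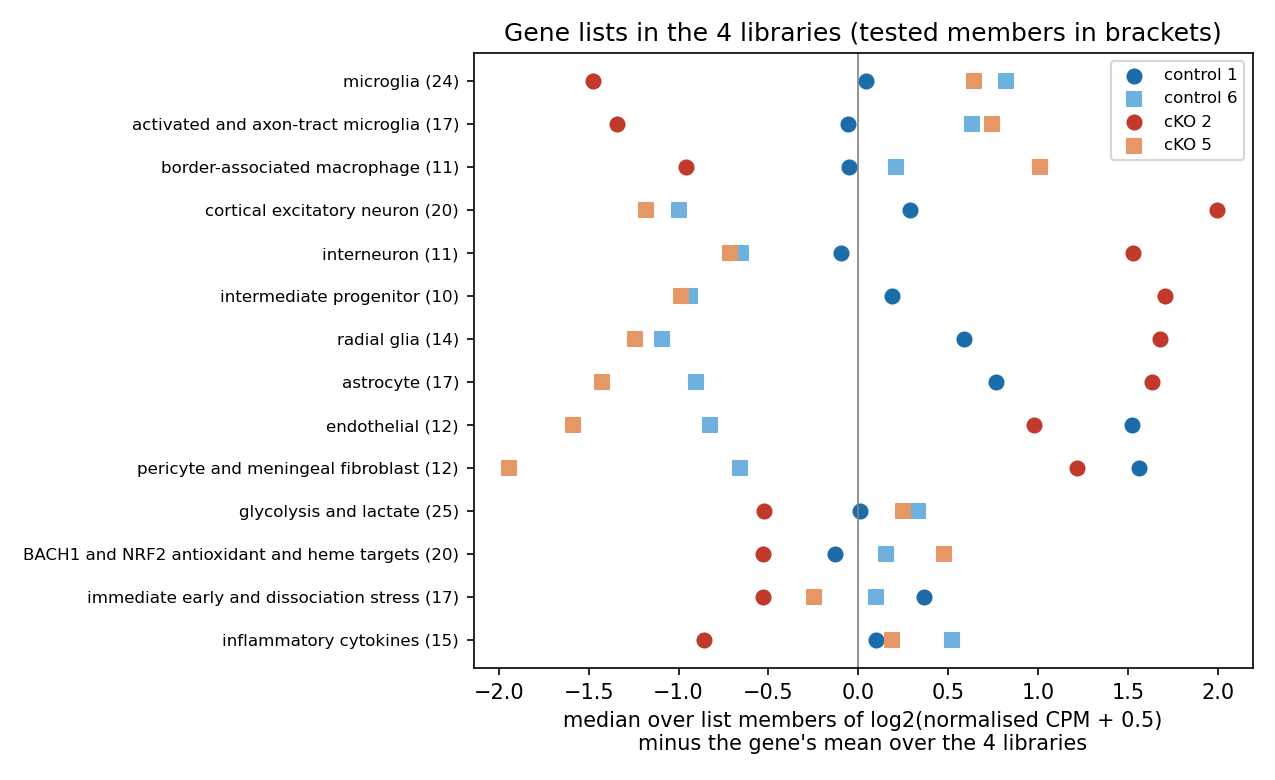
Median log2 deviation of each of 14 gene lists from the mean of the 4 libraries, 1 point per library. The microglia list is lowest in cKO 2 (−1.48) and the excitatory neuron list highest there (2.00), while the endothelial list is high in control 1 (1.52) and cKO 2 (0.98).

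Glycolysis and lactate genes fell as a group at the preset correlation (camera adjusted p = 0.0416; adjusted p = 0.894 with an estimated correlation), with 20 of 25 members negative and a median log2 fold change of −0.20. The pyruvate kinase gene Pkm had 2082 and 2517 CPM in the controls, 1727 CPM in cKO 2 and 2348 CPM in cKO 5. Slc2a1, the glucose transporter gene of brain endothelium and other cells, had 2278, 612, 1529 and 477 CPM. The list's deviations were 0.01 in control 1, 0.33 in control 6, −0.53 in cKO 2 and 0.25 in cKO 5, and without cKO 2 its median was 0.07. The call was also lost without control 1 or control 6 (camera adjusted p = 0.0868 and 0.375), without the filter on low counts (0.0617), with DESeq2 or edgeR's exact test (0.0702 and 0.0622), and with scaling on the microglial markers (0.443). The microglia list had its lowest value in the same library, at −1.48. Genes of the antioxidant and heme group repressed by BACH1 or induced by NRF2 had 13 positive and 7 negative members (median 0.09, camera adjusted p = 0.898). The ferritin gene Fth1 had 3256, 3235, 2407 and 4234 CPM and the peroxiredoxin gene Prdx1 662, 813, 508 and 1060.4 CPM. The deviations of this list were −0.53 in cKO 2 and 0.48 in cKO 5, so the cKO libraries lay on either side of the controls. Without cKO 2 the list's median was 0.45 and past the threshold as higher (camera adjusted p = 0.00108), and without cKO 5 it was −0.49 and past it as lower (0.0209). Cholesterol and fatty acid synthesis genes rose as a group (15 of 18 positive, median 0.32, camera adjusted p = 0.0150; adjusted p = 0.894 with an estimated correlation). Hmgcs1 had 302 CPM in cKO 2 and 96.45 CPM in cKO 5 against 153 and 79.0 CPM in the controls, and the median was −0.12 without cKO 2 and 0.21 without control 6, neither past the threshold. The list's deviations were 0.07 in control 1, −0.45 in control 6, 0.65 in cKO 2 and −0.27 in cKO 5, so cKO 5 lay between the controls, and the excitatory neuron list was also highest in cKO 2 (2.00). Nuclear electron transport chain genes had 21 positive and 9 negative members (median 0.06, camera adjusted p = 0.427), and TCA cycle genes 7 and 9 (median −0.02, camera adjusted p = 0.946). Hypoxia response genes had 11 of 15 negative members (median −0.23, camera adjusted p = 0.0670) and were past the threshold as lower in 2 of 11 other settings with all libraries. Genes of the unfolded protein and integrated stress response had 9 of 15 (median −0.03, camera adjusted p = 0.704).

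Immediate early and dissociation stress genes, which respond within minutes to stimulation or tissue handling, fell as a group (camera adjusted p = 3.2e-07; adjusted p = 0.894 with an estimated correlation). The median log2 fold change was −0.58, 14 of 17 members were negative, and 8 were lower in both cKO libraries than in both controls. Chance would give 2.83 if the libraries were interchangeable, and 1219 of all 15951 tested genes lay lower in this way. Members of 1 list can vary together, so the 8 of 17 is no test. Jun had 322 and 309 CPM in the controls and 246 and 202 CPM in cKO, and Zfp36, which destabilises cytokine messages, had 249 and 260 CPM against 79.95 and 158 CPM. The deviations were 0.37 and 0.10 in the controls and −0.53 and −0.25 in cKO. Unlike the other 13 lists past the threshold, this list stayed past it in the same direction when any 1 of the 4 libraries was left out (medians from −0.68 to −0.20). Inflammatory cytokine genes fell as a group as well (15 of 15 negative, median −0.62, camera adjusted p = 4.3e-04; adjusted p = 0.894 with an estimated correlation). Ccl3, a macrophage chemokine gene, had 280 and 373 CPM in the controls, 82.8 CPM in cKO 2 and 339 CPM in cKO 5, and the list's deviations were 0.10 in control 1, 0.52 in control 6, −0.86 in cKO 2 and 0.19 in cKO 5. The value in cKO 5 thus lay between the controls, and the microglia list was likewise lowest in cKO 2 (−1.48). Without cKO 2 its median was −0.23 (camera adjusted p = 0.726), and without control 6 it was −0.35 (0.0736). Interferon response genes had 11 of 15 negative members (median −0.14, camera adjusted p = 0.0670). They were past the threshold as lower in 2 of 11 other settings with all libraries. Astrogenic ligand, JAK-STAT, BMP and Notch genes, which the study connects to astrocyte formation, had 14 of 22 negative members, a median of −0.25 and a mean of −0.02 (camera adjusted p = 0.319), and were placed lower by camera without control 6 or cKO 2 (adjusted p = 0.0401 and 0.0325). In that list Stat3 had 293.5, 338, 202 and 292 CPM and the cytokine receptor gene Il6st 176, 156, 80.01 and 145 CPM in control 1, control 6, cKO 2 and cKO 5.

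**Figure D3:**
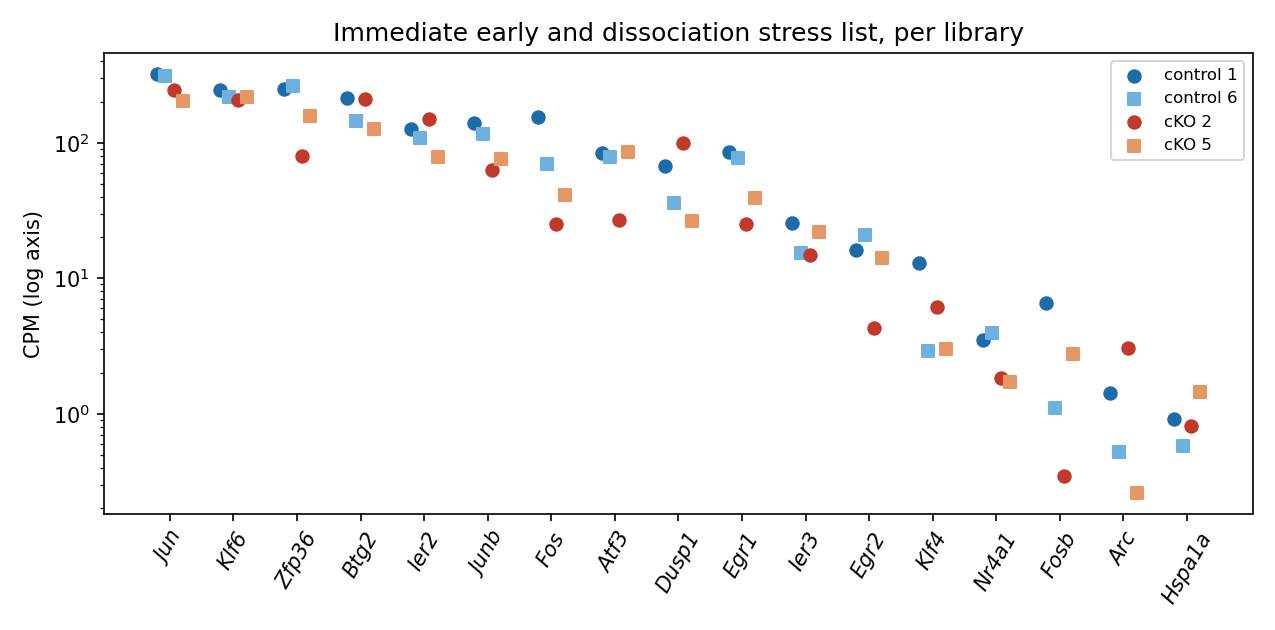
CPM (log axis) of the 17 tested immediate early and dissociation stress genes, 1 point per library coloured by genotype. Fos (156 and 70.1 CPM in the controls, 25.0 and 40.9 CPM in cKO) and Egr1 (85.5 and 77.1 against 25.2 and 39.1 CPM) are among the 8 genes lower in both cKO libraries.

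Cell cycle genes rose as a group at the preset correlation (20 of 23 positive, median 0.20, camera adjusted p = 0.0179, and 0.894 with an estimated correlation). Of the members, 8 were higher in both cKO libraries than in both controls, as were 1329 of all 15951 tested genes. Members of 1 list can vary together, so the 8 of 23 is no test. Cdc20, a mitotic exit gene, had 140 and 124 CPM in the controls and 213 and 152 CPM in cKO. The call was kept without cKO 2 (median 0.32) and lost without any other library, where the medians ran from 0.04 to 0.22. It was also lost without the filter on low counts (camera adjusted p = 0.0617), with DESeq2 (0.0702) and with edgeR's exact test (0.0660). The list's deviations were −0.13 and −0.04 in the controls, −0.05 in cKO 2 and 0.22 in cKO 5, so cKO 2 lay between the controls. The ribosomal protein list took every symbol starting with Rpl or Rps and a digit, so it can hold pseudogenes and S6 kinase genes. Of its members, 113 of 146 were positive (median 0.12, camera adjusted p = 0.152), with deviations of −0.32 in cKO 2 and 0.43 in cKO 5. Camera placed them higher without cKO 2 (adjusted p = 9.6e-09) and lower without cKO 5 (0.00440). Mitochondrially encoded genes had 4 positive and 9 negative members (median −0.08, camera adjusted p = 0.855), and histone genes 8 and 7 (median 0.25, camera adjusted p = 0.613). The 2 choroid plexus genes had a median of 0.07 while camera placed the list lower (adjusted p = 0.946). The 8 genes of brain regions outside the cortex had a median of −0.19, a mean of 0.34 and a camera adjusted p of 0.946. The 5 sex-linked genes had a median of 0.01 (camera adjusted p = 0.946).

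Annotation terms in the deposited tables were tested in the same way. Of 2842 terms with 10 to 500 tested genes, 7 were higher and 27 lower by camera at the preset correlation, and 0 with an estimated correlation (smallest adjusted p = 0.999). The higher terms included the AMPA glutamate receptor complex (24 genes, median log2 fold change 1.28, camera adjusted p = 0.00420), the postsynaptic membrane (159 genes, 0.61, 0.00707) and cerebral cortex neuron differentiation (14 genes, 0.89, 0.0281). The lower terms included inflammatory response (230 genes, −0.24, 0.00330), innate immune response (277 genes, −0.23, 0.00330), lysosome (207 genes, −0.17, 0.0339), the JAK-STAT cascade of growth hormone signalling (15 genes, −0.42, 0.0281), cell-matrix adhesion (62 genes, −0.41, 0.0219) and angiogenesis (191 genes, −0.22, 0.0457). Per library, the median deviation of the term's genes was highest in cKO 2 for 7 of the 7 higher terms and lowest there for 24 of the 27 lower ones. Without cKO 2, a fit added after seeing the data, camera kept none of the 34 terms past the threshold in its direction. The AMPA receptor term then had a median of −0.18 and inflammatory response 0.05.

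The libraries were then compared across all genes, without a test, since genes are not replicates. Control 6 and cKO 5 were the most alike pair (Pearson correlation of log2 CPM 0.950, Spearman 0.973), followed by control 1 and cKO 2 (0.930 and 0.945). The 2 controls correlated at 0.916 (Pearson), and the 2 cKO libraries were the least alike of the 6 pairs at 0.815. The first principal component held 71.4% of the variance and set control 1 (−50.1) and cKO 2 (−116) apart from control 6 (64.3) and cKO 5 (102). Neurod6 and Cldn5 were higher, and Spi1, a microglial transcription factor gene chosen after its values were seen, was lower in control 1 and cKO 2 (155 and 143 CPM) than in control 6 and cKO 5 (676 and 686 CPM).

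The authors deposited 1 table for each pairing of a cKO library with a control library, each setting a single library against another. Such a comparison concerns those libraries and not the genotypes. The authors' deposited table for cKO 2 against control 1 called 6501 of 20572 genes (4117 higher, 2384 lower), and that for cKO 2 against control 6 called 9503 of 20174 (6804 higher, 2699 lower). The authors' deposited table for cKO 5 against control 1 called 6829 of 19648 genes (1728 higher, 5101 lower), and that for cKO 5 against control 6 called 3895 of 18866 (1742 higher, 2153 lower). Of 17316 genes present in all of the authors' deposited tables, 169 were called higher and 106 lower in every table (1.59%). Gspt2 and Aqp4 were called higher in each of the authors' deposited tables. For Bach1 the authors' deposited tables gave log2 fold changes of −0.61 and −0.37 against control 1 and 0.47 and 0.71 against control 6, none of them called. Cx3cr1 was called lower in the authors' deposited tables of cKO 2 (log2 fold changes −2.54 and −2.79) and not called in those of cKO 5 (−0.65 and −0.90). Hk2 was likewise called in the authors' deposited tables of cKO 2 (−1.49 and −1.83) and not in those of cKO 5 (0.15 and −0.19).

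Calls in all 4 tables are not independent, because the tables share libraries. The authors' test is not given in the sources used here, so a binomial test of each pair's counts with a 2-fold minimum stood in for it, and it gave the same call as the authors' deposited tables for 98.6% to 99.1% of genes. By this rule 212 genes were called the same way in all 4 pairings (131 higher, 81 lower). In 100 simulated sets of libraries with no effect and a dispersion of 0.425, the mean was 991 genes and the range 899 to 1083. Each simulated gene varied by itself, without the likeness of control 1 to cKO 2 and of control 6 to cKO 5. The simulated number is therefore no measure of what these libraries give without an effect. Grouping the libraries otherwise gave 2522 genes for control 1 and cKO 2 against control 6 and cKO 5, and 114 for control 1 and cKO 5 against control 6 and cKO 2. In the authors' deposited tables that share no library, cKO 2 against control 1 and cKO 5 against control 6, 431 genes were higher in both (217 if the lists were independent), 245 lower in both (175) and 686 called in opposite directions (417). For the other such pair of the authors' deposited tables, cKO 2 against control 6 and cKO 5 against control 1, 237 were higher in both (384 if independent), 170 lower in both (526) and 3373 opposite (1343). The log2 fold changes of these pairs of tables correlated across genes at 0.09 and −0.36 (Pearson), and at −0.03 and −0.53 (Spearman).

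**Figure D4:**
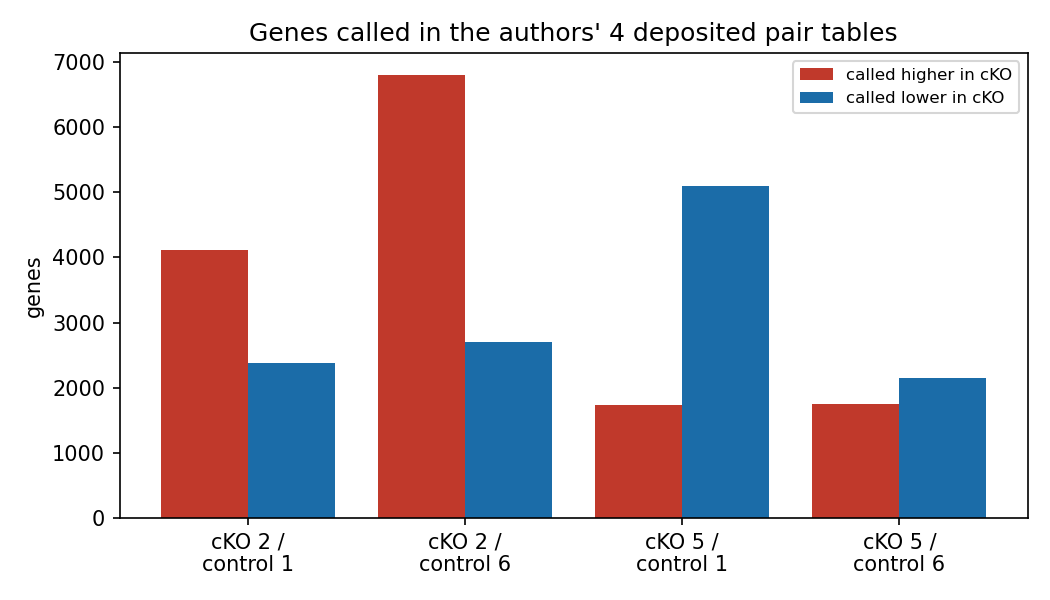
Bars from 0 giving the number of genes called higher and lower in each of the authors' deposited tables of 1 cKO library against 1 control library. The numbers called range from 3895 (cKO 5 against control 6) to 9503 (cKO 2 against control 6).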

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

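The tests of the pattern in cKO 2 were chosen after the result was seen, while the genes outside the tests were found by a rule applied to the tables. Some genes had no count for 1 cKO library, so they stood outside the tests. They had many reads in the other cKO library and few or none in the controls. Where both counts were known, a gene left out of a pair had at most 4 reads in that pair. The missing counts were therefore probably low, although they are not known. Trap1a had 149 reads in cKO 5 and 3 in each control. In cKO 2, Sprn had 133 reads, Syt13 76 and Gpr139 53, with none in either control. Kcnv1 had 74 reads there (4 and 2 in the controls), Ermn 69 (3 and 0), Zfp133-ps 56 (4 and 4), Myh14 54 (2 and 0) and Ddo 50 (4 and 0).

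The broader pattern was that neural markers were highest and microglial markers lowest in cKO 2. A lower microglia share alone would raise the markers of all other cell types alike, but against control 1 the 61 neural members were higher by a median of 1.52 (log2, SD 0.64) and the 24 vascular members lower (−0.54, SD 0.52), a gap of 2.06. Against control 6 the argument is weaker: both rose there, by 2.71 (SD 0.82) and 1.78 (SD 0.49), and the gap of 0.93 was only a little over the larger SD. A rise of neural markers shared by both cKO libraries was not seen. In cKO 5, 8.20% of the neural members were above both controls and 59.0% were below both. These members vary together and cKO 5 is 1 library, so an effect of the genotype is not excluded. More RNA of neural cells in cKO 2, which microglial isolation may have carried over, stays open: 95.1% of the neural members were highest there, among them Neurod6 at 1653 CPM, but this share restates the pattern and decides nothing. How the microglia were isolated is not given in the sources used here, so whether the pattern arose in the dissection, the isolation or the embryo stays open, and a biological difference between the embryos was not tested.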

How the results depend on the processing

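The covariate, the microglia-list scaling, limma-trend, and for terms the estimated correlation and the fits without 1 library, were chosen after seeing the data. The count of genes past the threshold was 0 in each direction in all settings (edgeR, DESeq2, limma), with an unadjusted p under 0.05 for 6 genes at a minimum of 10 CPM, 149 with no filter, 1210 with the neuron list score as a covariate (1 residual degree of freedom) and 46 with microglia-list scaling. Among settings that kept all 4 libraries, 347 values of lists and of single genes other than Bach1 (each counted once per setting) kept their direction and side of the threshold, 19 kept only the direction and 10 reversed. Of the values for the main comparisons, the log2 fold change of Bach1 among them, 64 stayed the same, 3 moved and 1 (Bach1) reversed. Single genes could differ only in direction, since none was past the threshold in any setting. The fit without sex-linked genes was the main fit with those genes removed, so its other genes could not change. Many of the 64 were counts of 0 genes that stayed at 0. For single genes these tallies are therefore weak evidence of stability. The number of lists past the threshold went from 14 to 0 with an estimated correlation and to 0 with fry. That of terms went from 34 to 0 with an estimated correlation. The estimated correlation was 0.979 for the microglia list, 0.987 for excitatory neurons and 0.989 for endothelium. It was smaller for immediate early genes (0.0856), glycolysis (0.0716) and cell cycle (0.0621), though above the preset 0.01. The preset thus took the members of these lists as more independent than estimated. Why fry gave 0 was not tested. Calls in all 4 of the authors' deposited tables were 363 by adjusted p with a 2-fold change, against 275.

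The log2 fold change of Hmox1 was −0.41 in limma-voom and −0.43 in limma-trend, and that of Gapdh −0.0985 and −0.0873; the cause was not tested. The radial glia list median was −0.35 with the neuron list score as a covariate, which takes neural differences out by construction. Microglia-list scaling, under which the median of all genes was 1.10 against 0.03, gave 0.70 for Bach1, 1.19 for Cd248, 0.45 for Ldha, 0.15 for Sigirr, 0.27 for Lrch1 and 0.0257 for Prdm1; apart from that shift, the cause was not tested.

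Leaving out 1 library gave these ranges of log2 fold change: Bach1 −0.46 to 0.45, Hk2 −1.93 to 0.0670, Ldha −1.02 to 0.26, Gapdh −0.75 to 0.56, Hmox1 −1.85 to 1.00 and Cd248 −3.76 to 0.67. List medians ran from −0.70 to 0.0726 for glycolysis, −0.12 to 0.81 for cholesterol synthesis, 0.0425 to 0.32 for cell cycle, −2.53 to 1.06 for extracellular matrix, −1.95 to 0.22 for microglia and −1.67 to 0.49 for activated microglia. They ran from −1.22 to 2.17 for radial glia, −0.93 to 2.22 for intermediate progenitors, −0.96 to 2.22 for excitatory neurons, −0.49 to 1.96 for interneurons and −2.29 to 0.95 for endothelium. The number of lists past the threshold ran from 8 (without control 6) to 19 (without cKO 2). Of the 14 lists past it, 3 kept their direction in each of these fits (immediate early genes, cytokines and Cajal-Retzius cells), and 6 were past it the other way in at least 1. Of the 20 lists not past it, 14 were past it in at least 1 of these fits, 7 of them in both directions. The number of terms past it was 79 without control 1, 49 without control 6, 57 without cKO 2 and 304 without cKO 5, and of the 34 terms past it with all libraries 19, 3, 0 and 30 were kept. Libraries could not be paired by replicate, because the genotypes share no replicate number, and sex was not used as a block. RPKM settings were not run, as the tables used hold CPM, and an erythroid covariate was not run. Depth was alike across libraries; the spread between libraries of a genotype limits these results more than counting error.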

Other observations

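The tests of the immediate early genes and of Cx3cr1 in this part were chosen after the result was seen, as were the genes in the next paragraph. Of the 20 tested members of the BACH1 and NRF2 list, Gclm, Gsr and Txnrd1 had their highest values in cKO 5. So did Hmox1, Fth1 and Prdx1. Ftl1 was highest in control 6 (3112 CPM against 2845 CPM in cKO 5) and Sqstm1 in control 1 (683 against 616 CPM). Gclm, Gsr and Txnrd1 were outside the rule for named genes and are examples only. The whole list was not past the threshold (camera adjusted p = 0.898), with deviations of −0.53 in cKO 2 and 0.48 in cKO 5. Gclm, a subunit gene of glutathione synthesis, had 11.05 and 20.3 CPM in the controls, 9.53 CPM in cKO 2 and 56.5 CPM in cKO 5, and the glutathione reductase gene Gsr had 36.2, 50.1, 36.6 and 82.8 CPM. Txnrd1, the thioredoxin reductase gene, was higher in both cKO libraries, at 120 and 139 CPM against 72.4 and 89.3 CPM, a log2 fold change of 0.61 ± 0.37 that is not past the threshold (edgeR adjusted p = 0.9997). The border-associated macrophage genes Pf4 and Lyve1 were also highest in cKO 5, with Pf4 at 14.1 CPM against 2.63, 3.42 and 2.83 CPM in control 1, control 6 and cKO 2, and Lyve1 at 18.1 CPM against 3.95, 5.86 and 3.004 CPM.

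2 microglial genes, C1qc and Spi1, differed more between the 2 pairs of alike libraries than the other members compared. The direction was the same, and all 24 tested members of the list were lowest in cKO 2. The complement gene C1qc had 730 and 725 CPM in control 1 and cKO 2 and 4315 and 4278 CPM in control 6 and cKO 5, a 5.90-fold difference of these pairs. Spi1 differed 4.56-fold between them, while C1qb differed 2.36-fold and Csf1r 1.89-fold. No explanation was tested.

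The immediate early list had a lower median in both cKO libraries, and 8 of 17 members were lower there than in both controls (47.1%). Chance gives 16.7% one way if libraries are interchangeable and members vary independently. Other members went another way, with Dusp1 and Ier2 highest in cKO 2 (99.8 and 149 CPM) and Atf3 highest in cKO 5 (85.4 CPM). A lower microglia share is argued against for cKO 5, where the immediate early median was −0.56 (SD 0.52) against the controls and the microglia median 0.21 (SD 0.40), a gap of −0.78. For cKO 2 it remains possible, since the microglia median there was −1.88 and that of the immediate early genes −0.63, a gap of 1.25. Tissue handling or dissociation that differed between the genotypes could lower them as well. It cannot be told apart from loss of Bach1, because it would follow the same libraries. Shares of cell types other than microglia were not tested for this list. The endothelial list, for instance, was at 1.52 and −0.83 in the controls, 0.98 in cKO 2 and −1.59 in cKO 5.

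Cx3cr1 was the 1 of 24 microglial markers below both controls in both cKO libraries. A lower microglia share alone is argued against. Cx3cr1 lay −2.88 SD from the mean of the other 23 markers in cKO 5 (−0.70 against 0.32). In cKO 2 it lay −4.27 SD from the mean of the others (−2.90 against −1.87), with 0 of 23 as low in either library. The other markers also fell in cKO 2, so a lower share there can account for part of the fall. Relative to the median of the other markers, Cx3cr1 was at 3.20 and 2.89 (log2) in the controls and 2.18 and 2.00 in cKO, a mean difference of −0.95. A Cx3cr1 copy replaced by the Cre allele, as in knock-in drivers, is a candidate explanation, as the driver is named Cx3 in the labels; it cannot be told apart from an effect of Bach1, since the driver and the deletion stand in the same 2 libraries.

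The 4 libraries allow 3 splits into 2 and 2, which are too few for a share under 0.05, and all 3, the real one included, gave at least 49 genes. The real split had 49 genes at an unadjusted p under 0.05 (edgeR), control 1 and cKO 5 against control 6 and cKO 2 had 75, and control 1 and cKO 2 against control 6 and cKO 5 had 4319. The latter count points to a structure of the samples other than genotype, and in that split the smallest adjusted p in edgeR was 0.0573. Sex does not follow it, as the libraries with Xist reads were control 1 and cKO 5. The split with 75 genes does follow sex, and 0 genes were past the threshold in it (smallest adjusted p in edgeR 0.9999). Not even Xist or Ddx3y was past it there, so a count of 0 does not show that no gene differs.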
